A study of Mus musculus domesticus with 31 samples.

How the data were processed

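RNA from the striatum of 31 adult male mice (Mus musculus domesticus) of generation 66 of a selection experiment was sequenced. Per the labels, 16 mice came from 4 lines bred for high voluntary wheel running (L3, L6, L7 and L8) and 15 from 4 randomly bred control lines (L1, L2, L4 and L5), with 4 mice per line except L1, which had 3. Mice had wheels for 6 days from about 35 days of age. On day 7 the wheel was blocked, and the whole striatum, dorsal and ventral, was dissected 1 to 4 hours after lights off from a section about 1.7 mm thick. Libraries were made with a strand-specific TruSeq kit and read for 101 cycles from each end in 4 lanes. The lane of each library is not given in the sources used here, so lane and group could not be separated.

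For each mouse the authors deposited 2 files of raw counts, 1 of read counts per gene and 1 of read counts per exon bin, a bin being a stretch of exon that no annotated transcript boundary divides. Tools named per the submitters' processing notes were CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, SAMtools 0.1.19 and HTSeq 0.6.1, with the mouse builds GRCm38 and mm10. The notes used here give these tools no role or order, and the strand setting of the counting is not given in the sources used here. Reads of genes that overlap, of antisense partners and of pseudogenes near-identical to a parent gene could therefore be split between gene models, and such genes are reported as uncertain. A read pair that spans several bins can enter the count of each, so bin totals exceed gene totals.

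The gene files held 39179 gene identifiers, of which 37693 matched the GENCODE mouse M21 annotation of GRCm38 and 1486 did not. Symbols and coordinates come from that annotation. At least 1 read was counted for 26385 genes. The bin files held 360776 bins, 26317 of them in gene models merged from overlapping genes. Summary lines of the count files were left out of library sizes and tests. Read pairs outside any gene made up 6.73 to 8.93% of the pairs per library, pairs ambiguous between genes 1.28 to 3.33%, and pairs aligned to more than 1 place 5.83 to 6.84%. Gene counts per library ranged from 34146382 to 55396532. Within lines, no pair of libraries was a repeat of the other: over 45 pairs, the lowest chi-square per degree of freedom was 9.68 over genes with at least 20 counts.

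Everything from here on was computed from the deposited counts. Selection was applied to lines, so the line was taken as the replicate. Counts were summed over the mice of each line and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM factors, the filterByExpr filter by group, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The same test on single mice was run second, and its p-values treat mice of 1 line as independent. Control mice were compared between the 4 control lines, and selected mice between the 4 selected lines, with an F test on the line terms. The slope on the labelled running distance of each mouse, in km per 24 h, was tested with line as a covariate, and so was the difference of that slope between selected and control mice. Exon usage, the share of a gene's reads that falls in each bin, was tested on bin counts summed per line with diffSpliceDGE of edgeR and a Simes test per gene. Running distance was compared by an exact permutation test of line means.

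Gene lists were tested on line sums with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry beside it. The 31 lists covered monoamine receptors and chromatin regulators, which the series title names, other receptors, channels and signalling genes of the striatum, markers of striatal and other cell types, immediate early, clock, stress and immune genes, and ribosomal and respiratory chain genes. Of their members 734 genes were measured, 20 of them in more than 1 list. A list score is the mean log2 CPM of its members, centred over the lines, with a prior count of 2. DESeq2 1.42.0, R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were also used.

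The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For selection, the rule named up to 10 genes per direction with adjusted p of at most 0.05, a mean log2 CPM of at least 0 and the largest fold changes, filled up to 10 with the lowest unadjusted p. It also named Drd1, Drd2, Drd3, Htr1b, Htr2a and Fos, up to 4 members of lowest p of each list discussed, the 8 genes of lowest p in each test between lines and in exon usage, and the 5 of lowest p per direction for running distance. Mfsd7a, called with a mean log2 CPM of -0.18, entered through its unadjusted p. Members of lists that the rule did not pick were named after their values were seen.

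The tests were checked on simulated counts drawn from the real means and library sizes, with 200 changed genes. The changed genes were drawn only from those above a floor on the mean count. At log2 changes of 0.5, 1 and 2 the line test on 18604 genes called 59.7, 89.6 and 95.5% of the changed genes, and 6.9% of its calls were false. The mouse test on 16539 genes called 94% of those changed by 0.5, with 4.9% of calls false. The simulated mice carried no differences between lines of a group, so the 4.9% does not cover false calls from such differences. The test within lines on 17390 genes called 97% of genes whose slope was 0.5 per 5 km. Smaller slopes were not simulated, and most genes named for running distance had smaller ones, such as 0.0226 log2 per km for Inpp5j. The exon usage test on 14877 genes called 38.8, 83.6 and 98.5% of the genes in which a bin was changed by 0.5, 1 and 2, but 32.1% of its calls were false, above the 5% aimed at. A list of the 31 raised by a log2 value of 0.3 was the 1 list called. Simulated genes were drawn independently, so this check could not show false calls among lists whose members vary together. In the real lines the estimated correlation was 0.483 for heat shock genes and 0.722 for cytosolic ribosomal protein genes.

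Alternatives were other normalizations (DESeq2 size factors, or library size alone), other tools (DESeq2, limma on line means, limma-voom with line as a random block), no filter or a stricter filter on low counts, autosomes only, leaving out each line in turn, and leaving out the L7 mouse of lowest running distance. Leaving out the L5 mouse with the highest share of ambiguous pairs was added after the data were seen, as were the L7 mouse for the test over mice and the unfiltered test of running distance.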

Results

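The data were 31 striatum libraries, 15 from control lines and 16 from lines bred for high wheel running. Gene counts had a median of 46101102 per library, with 43506624 ± 5341262 (SD, n = 15 mice) in control and 46624170 ± 5509185 (SD, n = 16 mice) in selected mice. Mitochondrial genes took 10.4% ± 1.17 of the counts in control and 10.9% ± 1.05 in selected mice. Ribosomal RNA genes took 0.631% ± 0.0916 and 0.726% ± 0.101 (SD over the same mice). Levels are given as CPM, counts scaled to a fixed library total.

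Selected lines ran farther in the 24 h before the wheel was blocked. The 4 selected lines averaged 15875 ± 2133 m and the 4 control lines 4065 ± 1218 m (SD, n = 4 lines), a ratio of 3.91, and all 4 selected lines lay above all control lines. The exact permutation test of the line means gave p = 0.0286, two-sided, the smallest value that 70 assignments allow. Line L6 ran 18860 ± 1637 m and L2, the farthest control line, 5756 ± 2190 m (SD, n = 4 mice each). Within L7 the 4 mice ranged from 1584 to 26049 m.

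**Figure D1:**
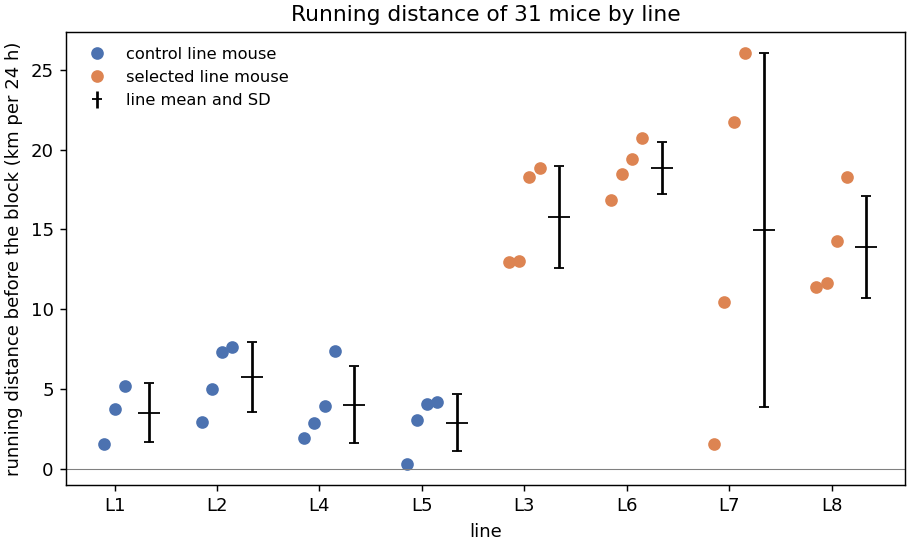
Running distance of each of the 31 mice (km per 24 h, vertical axis) by line, control lines on the left and selected lines on the right, with the mean and SD of each line in black. The selected line means lie between 13902 and 18860 m, and the control line means between 2922 and 5756 m.

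The first question was which striatal genes differ between lines bred for running and control lines. With lines as replicates, 2 genes fell in the selected lines. Mfsd7a (ENSMUSG00000029490, a protein-coding gene of the major facilitator family of transporters, chromosome 5, 108441054 to 108448891, GRCm38) went from 1.27 CPM ± 0.138 in control lines to 0.487 ± 0.0517 in selected lines (SD, n = 4 lines each). Its log2 fold change was -1.38 (SE 0.126), with edgeR adjusted p = 0.0159. Gm8707 (ENSMUSG00000098093, a transcribed processed pseudogene, chromosome 9, 41651893 to 41655282) went from 4.71 CPM ± 0.577 to 2.16 ± 0.116, a log2 fold change of -1.13 (SE 0.0973) and adjusted p = 0.0159. For both genes all 4 selected lines lay below all 4 control lines. Gm8707 lies inside the span of the noncoding gene 3110039I08Rik and is a retrocopy, so its level is uncertain.

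Among 18620 genes tested no gene rose in this fit, and 1173 had an unadjusted p under 0.05 in edgeR where 931 were expected. In 738 genes, 3.96% of those tested, the 4 selected lines all lay on 1 side of the control lines, against 2.86% by chance. Of the 35 divisions of the lines into 4 and 4, 10 gave at least 1173 (up to 1995) and 6 at least 738 (up to 1123). Without L1, L6, L7 or L8, edgeR called 0 genes, with 1403, 853, 1040 and 1208 at unadjusted p under 0.05, and it called 1 without L3 (5031434O11Rik), 6 without L2 (4 of them higher in selected lines) and 7 without L4 (1 higher). Without L5 it called 2, with 1 higher. DESeq2 on the same line sums called 50 genes, 26 higher and 24 lower, and limma-voom on mice with line as a random block 45, 20 higher and 25 lower.

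The other 18 genes named by the rule did not pass the threshold over lines, though in each the 4 selected lines stood apart from the 4 control lines. The 10 with higher values included Carnmt1, the methyltransferase that makes anserine from carnosine (7.80 CPM ± 0.274 in control and 10.02 ± 0.413 in selected lines, log2 fold change 0.36, SE 0.0493), and Gak, a kinase of clathrin uncoating (104 ± 1.72 and 118 ± 1.44, 0.18, SE 0.0252). Both had adjusted p = 0.174. Shisa2, which acts on the maturation of growth factor receptors, had 8.67 CPM ± 1.41 in control and 13.7 ± 0.707 in selected lines. Log2 fold changes were 0.34 for Rnd3, 0.28 for Dcun1d1, a protein of the neddylation pathway, 0.21 for Rhbdl3 and 0.21 for Sat1, the acetyltransferase of polyamine breakdown. They were 0.24 for Peli1, a ubiquitin ligase of innate immune signalling, 0.27 for Hbegf, a ligand of the epidermal growth factor receptor, and 2.04 for Mgst2, a microsomal glutathione transferase of 0.0662 CPM in control and 0.282 in selected lines.

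Of the named genes with lower values, the noncoding transcript 5031434O11Rik had the largest difference. It stood at 6.23 CPM ± 0.184 in control lines and 1.00 ± 0.686 in selected lines (SD, n = 4), a log2 fold change of -2.63 (SE 0.383, adjusted p = 0.28). L3 stood apart at 2.03 CPM, and without it the log2 fold change was -3.23 (SE 0.076, adjusted p = 2.01e-06). Of 18 alternatives, 4 called the gene: the fit without L3, DESeq2 (4.36e-11), limma on line means (0.0177) and limma-voom with line as a random block (7.51e-12). The other alternatives did not call it, with adjusted p up to 0.69. Its span on chromosome 3 (51560035 to 51567117) overlaps the start of Setd7, a histone methyltransferase gene (51515319 to 51560879), for which the log2 fold change was -0.09 (SE 0.041, adjusted p = 0.807). Tmed5, a cargo protein of the early secretory pathway, went with 39.4 CPM ± 2.39 and 30.9 ± 0.779, a log2 fold change of -0.35. Idua, the lysosomal iduronidase, had -0.31, Bmp3, a bone morphogenetic protein, -0.38, and Gpr21, an orphan receptor, -0.60. Unc45b, a myosin chaperone, had -0.50, Haghl -0.20 and Cdk11b, a kinase of transcription and splicing, -0.14. Of the named genes, 5031434O11Rik overlaps Setd7, Tmed5 overlaps Mtf2, Idua overlaps Dgkq and Slc26a1, Gpr21 overlaps Rabgap1 and Strbp, Haghl overlaps Narfl and Dcun1d1 overlaps Gm15952, so the levels of these genes are uncertain.

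**Figure D2:**
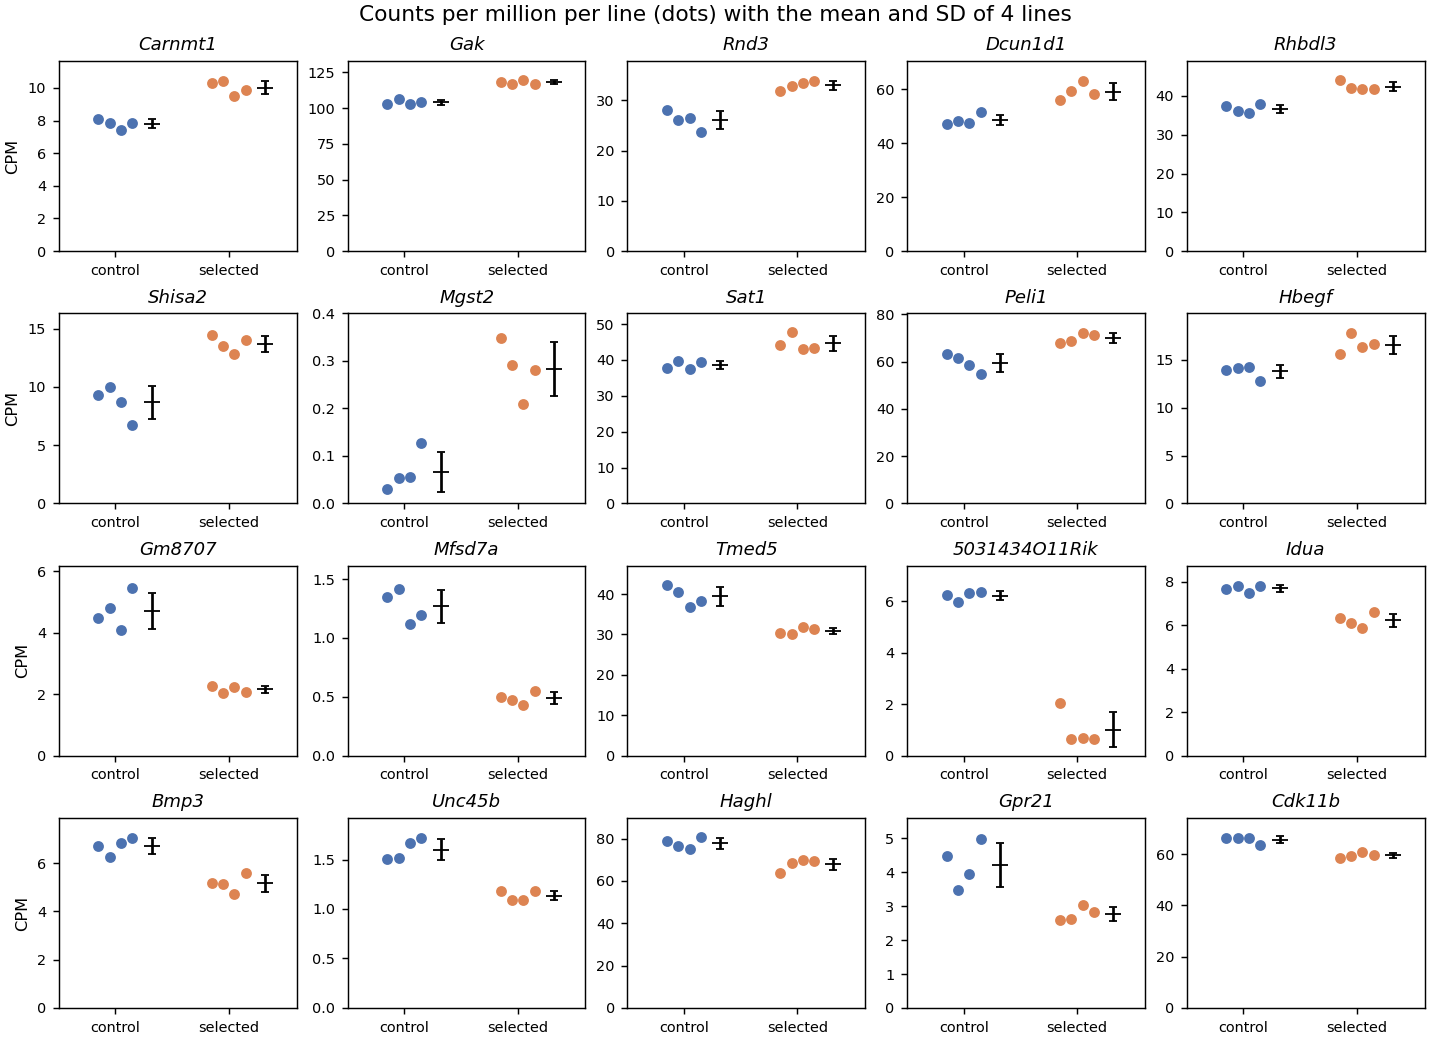
CPM of the 20 genes named for the selection comparison, each dot 1 line (vertical axes start at 0), with the mean and SD of 4 lines in black. Mfsd7a and Gm8707 were the 2 that passed the adjusted threshold, at 0.487 against 1.27 CPM and 2.16 against 4.71 CPM.

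Several named genes lie close together. Tmed5, Mfsd7a, Gak and Idua lie between 108106366 and 108684557 of chromosome 5, with Pcgf3, a Polycomb ring finger gene (log2 fold change 0.11, SE 0.027, adjusted p = 0.738), between them. Mgst2 and 5031434O11Rik lie on chromosome 3 with Ndufc1, a subunit of respiratory complex I (log2 fold change 0.17, SE 0.043). Among the 100 tested genes of lowest p, 22 pairs lay within 1 Mb of each other, where random sets of 100 tested genes held 7.81 ± 3.01 (SD over 10000 sets) and 22 of the 35 divisions of the lines held at least as many (up to 223).

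**Figure D3:**
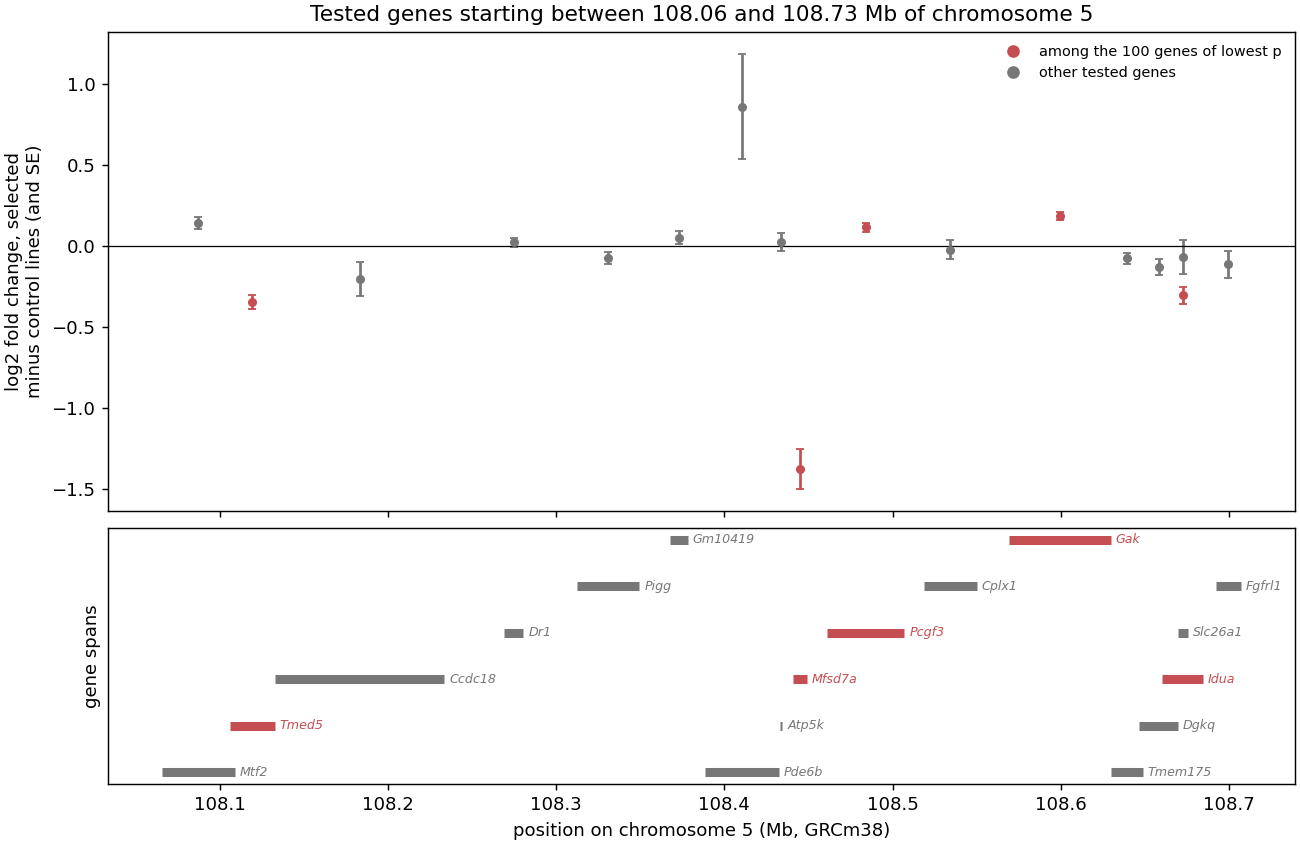
Log2 fold change with its SE (upper panel) of the tested genes of a stretch of chromosome 5 against position (Mb, GRCm38), with the gene spans below and genes among the 100 of lowest p in red. Mfsd7a lies at -1.38, Tmed5 at -0.35 and Idua at -0.31, while Gak lies at 0.18 and Pcgf3 at 0.11.

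With single mice as replicates, 308 of 16485 genes passed, 143 higher and 165 lower in selected mice. Of the 19 named genes tested this way, 18 passed, Bmp3 being the exception (adjusted p = 0.178). In limma-voom on mice with line as a random block, some of these, such as Rnd3 and Rhbdl3, did not pass (adjusted p = 0.107 and 0.112). Carnmt1, Gak, Dcun1d1 and Shisa2 did (0.000175, 0.00039, 0.00273 and 0.0417). That fit takes a single correlation within lines for all genes (0.151). It can therefore allow too little for line in genes whose lines differ more. All 308 had the same sign over lines, and 297 had an unadjusted p under 0.05 there. The line sums hold the same counts, so neither this nor the 18 named genes is independent support. Between lines of at least 1 of the groups, 72 of the 308 also differed. The p-values of the edgeR fit on single mice treat mice of 1 line as independent, and its count was 82 without L5, 137 without L6, 199 without L4 and 727 without L2. DESeq2 on the same mice called 546, 284 higher and 262 lower. Other divisions of the 8 lines into 4 and 4 gave up to 545 genes.

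**Figure D4:**
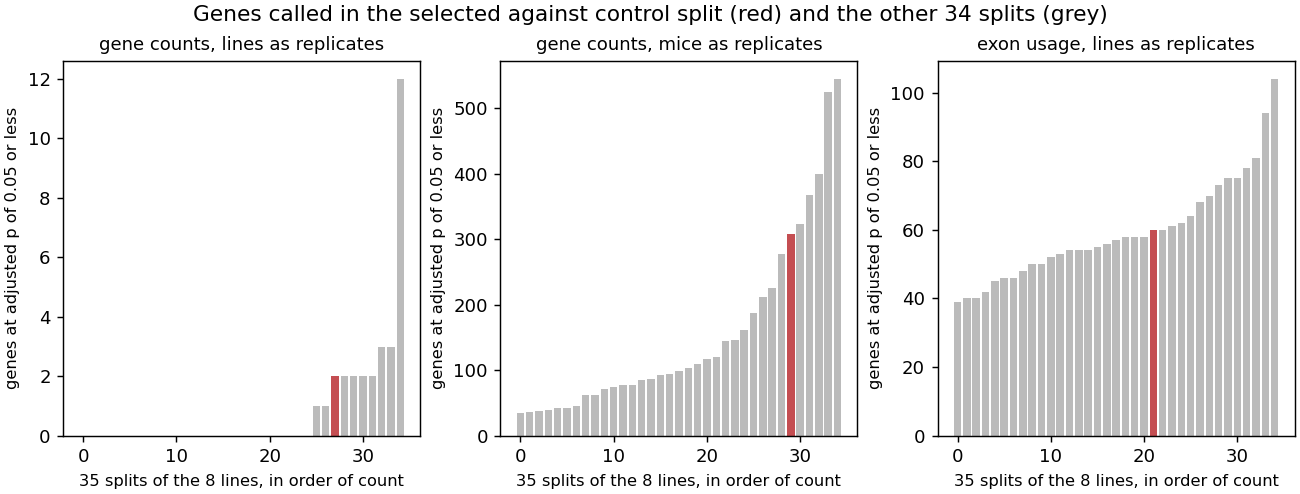
Genes or gene models passing the adjusted threshold (vertical axes) in each of the 35 divisions of the 8 lines into 4 and 4, in order of count, with selected against control in red. That division gave 2 genes over lines, 308 over mice and 60 in exon usage, and the highest of the others gave 12, 545 and 104.

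The second question concerned groups of genes, by 31 lists fixed beforehand. Over lines, 8 lists passed camera at the preset correlation, 6 with higher and 2 with lower values in selected lines. For each of the 8, adjusted p = 0.906 with an estimated correlation, and fry gave an adjusted p of 0.73, so no list passed either of those tests (0 and 1 of the 31 lists had an unadjusted p under 0.05, the 1 being heat shock genes). In edgeR no member of these 8 lists passed over lines, adjusted over all genes or adjusted over the list alone, and 32 memberships had an unadjusted p under 0.05. Over mice, 9 of the 734 measured genes of the 31 lists passed among all genes, where 1.87% of all genes tested over mice did. None of the 9 passed over lines among all genes, and their p-values over mice treat mice of 1 line as independent. In none of the 8 did the scores of all 4 selected lines lie beyond those of all control lines (0 to 3 of the 4 did), and the exact test of the line scores gave an adjusted p of 0.971 for each.

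Heat shock and unfolded protein response genes, the chaperones and folding enzymes of stressed cells, were higher on average in the selected lines. The score of control line L2 (0.091) still lay above those of L3 (0.077), L6 (0.072) and L8 (0.056), and the exact test gave an unadjusted p of 0.114. All 25 measured members had a positive log2 fold change (median 0.13, camera adjusted p = 5.67e-10, and adjusted p = 0.906 with an estimated correlation). Dnajb1 was at 52.2 CPM ± 4.16 in control and 60.2 ± 0.83 in selected lines, Hspb1 at 3.44 ± 0.892 and 4.81 ± 0.085, Hspa1b at 6.05 ± 0.379 and 7.38 ± 0.844, and Dnajb5 at 148 ± 13.2 and 167 ± 8.88. Over mice Hspb1 rose (log2 fold change 0.50, adjusted p = 0.0144), and 7 members passed when adjusted over the list alone.

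Immediate early genes, which neurons switch on within minutes of activity, also stood higher, with 25 of 29 members above 0 (median 0.13, camera adjusted p = 0.000609, and adjusted p = 0.906 with an estimated correlation). Fosl2 had 37.4 CPM ± 5.88 in control and 51.0 ± 5.69 in selected lines, Egr2 11.1 ± 1.75 and 14.6 ± 2.22, and Nptx2 39.1 ± 3.30 and 44.6 ± 3.02. Nr4a2 went the other way, with 49.5 ± 6.79 and 40.1 ± 3.77. Fos was at 17.1 ± 3.29 and 18.8 ± 4.88. Over mice Fosl2 rose by a log2 value of 0.46 (adjusted p = 0.0227), and 4 members passed adjusted over the list alone. The list's adjusted p was 0.0631 without L2.

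Circadian clock genes had 19 of 21 members above 0 (median 0.06, camera adjusted p = 0.00131, and adjusted p = 0.906 with an estimated correlation). Bhlhe40 had a log2 fold change of 0.22 (SE 0.0649), Cry1 0.16 (SE 0.0774), Per1 0.18 (SE 0.0974) and Per2 0.21 (SE 0.132), none of them past the threshold over lines or mice, and Bhlhe40 overlaps a noncoding gene and is uncertain. Without L5 the score difference went from 0.083 (SE 0.053) to 0.039 (SE 0.031), and the list's adjusted p was 0.139. Cytosolic ribosomal protein genes had 52 of 57 members above 0 (median 0.04, camera adjusted p = 7.31e-05, and adjusted p = 0.906 with an estimated correlation). Over mice Rps19 rose by 0.26 (adjusted p = 0.0142) while Rps2 fell by 0.56 (adjusted p = 0.0293). Many of these genes have near-identical pseudogenes, so their counts are uncertain. Without L6 the score difference went from 0.042 (SE 0.047) to 0.01 (SE 0.038), and the list's adjusted p was 0.286.

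Of the chromatin regulators, 33 of 49 remodeller genes (median 0.02, camera adjusted p = 0.0241) and 36 of 57 histone methyltransferase and demethylase genes (median 0.03, camera adjusted p = 0.0251) lay above 0, both with adjusted p = 0.906 with an estimated correlation. Baz1a, the ISWI subunit ACF1, stood out among them with 7.28 CPM ± 1.13 in control and 10.2 ± 0.584 in selected lines (log2 fold change 0.49, SE 0.106, adjusted p = 0.704), and it rose over mice by 0.50 (adjusted p = 0.00271). Setd3, an actin histidine methyltransferase placed in the list for its SET domain, rose over mice by 0.13 (adjusted p = 0.0347). Dpf2, Actl6a and Mbd2 had log2 fold changes of 0.10, 0.18 and 0.12, Kmt5a, Kdm2a and Setd7 of 0.13, 0.07 and -0.09. Actl6a and Setd7 overlap other genes and are uncertain. Leaving out L2, L4, L5, L6 or L8 ended the call of the remodellers (adjusted p = 0.169, 0.085, 0.19, 0.0813 and 0.0914), and leaving out L2, L4, L5 or L6 that of the methyltransferases and demethylases (0.185, 0.102, 0.188 and 0.217). Histone acetyltransferases and deacetylases (adjusted p = 0.626) and DNA methylation genes (0.155) did not pass, though DNA methylation genes did, with higher values, without L1 (0.00611) or L3 (0.0475).

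Antigen presentation and interferon genes stood lower in the selected lines, with 22 of 24 members below 0 (median -0.31, camera adjusted p = 0.000146, and adjusted p = 0.906 with an estimated correlation). Gbp3, an interferon-induced GTPase, was at 2.85 CPM ± 0.563 in control and 2.21 ± 0.225 in selected lines, Isg15 at 0.647 ± 0.159 and 0.462 ± 0.0941, and the class I gene H2-T23 at 3.86 ± 0.577 and 2.54 ± 1.03. Oasl2 had a log2 fold change of -0.33 (SE 0.155). No member passed over lines or mice in edgeR, with 2 at unadjusted p under 0.05 over lines, and 9 of the 24 differed between selected lines and 4 between control lines. Class I genes are near-identical to each other, and their counts are uncertain.

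Markers of cortical excitatory neurons, which a striatal dissection can carry along, stood lower, with 13 of 18 members below 0 (median -0.07, camera adjusted p = 0.00904, and adjusted p = 0.906 with an estimated correlation). Tbr1 was at 72.4 CPM ± 3.91 in control and 63.2 ± 3.50 in selected lines and Emx1 at 5.19 ± 0.405 and 4.34 ± 0.167, whereas Lamp5 had a log2 fold change of 0.20. On mice with line as a random block the list's adjusted p was 0.669, and without L2, L3 or L6 it was 0.185, 0.0535 or 0.0925.

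**Figure D5:**
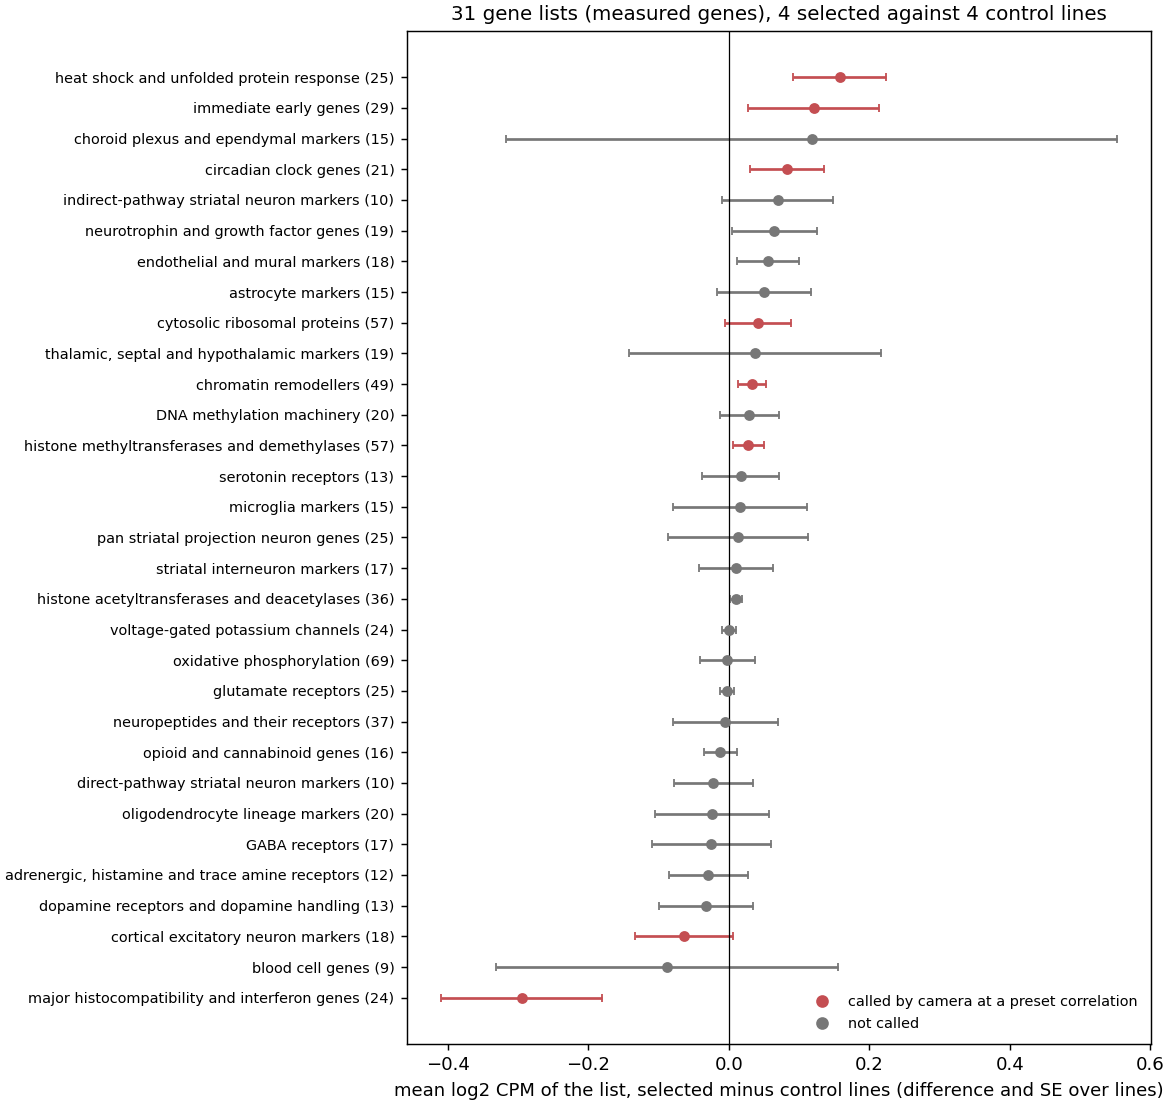
Difference of the mean log2 CPM of each of the 31 lists between selected and control lines (horizontal axis, with SE over lines), with the number of measured genes in parentheses and the 8 lists that passed camera at the preset correlation in red. Heat shock genes lie at 0.158 and antigen presentation and interferon genes at -0.295.

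The series title names monoamine receptors, and none of their 3 lists passed. Camera adjusted p was 0.274 for dopamine receptors and dopamine handling, 0.827 for serotonin receptors, and 0.626 for adrenergic, histamine and trace amine receptors. Drd1 was at 236 CPM ± 26.4 in control and 238 ± 27.9 in selected lines, Drd2 at 118 ± 13.5 and 121 ± 20.0, Drd3 at 2.09 ± 0.304 and 1.87 ± 0.512 and Htr2a at 25.1 ± 4.28 and 25.6 ± 1.98 (SD, n = 4 lines). Htr1b was at 84.7 ± 19.3 and 108 ± 14.7, a log2 fold change of 0.35 (SE 0.164). It did not pass over lines (adjusted p = 0.807) or mice (0.0724), and passed over mice when adjusted over the list alone (0.0246), though it overlaps D430036J16Rik and is uncertain. Th, the rate-limiting enzyme of dopamine synthesis, was at 8.16 ± 0.407 and 6.72 ± 0.378, a log2 fold change of -0.28 (SE 0.0595). It fell over mice (adjusted p = 0.0406) and over lines when adjusted over the list alone (0.0145), but not over lines among all genes (0.704). Htr1f had a log2 fold change of -0.22 (SE 0.0798) and Adra1a of -0.17 (SE 0.0778).

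The third question was how far lines of 1 group differ from each other, which is the background of the selection comparison. Between the 4 control lines 1360 of 17119 genes differed, and between the 4 selected lines 1181 of 16921 did, both in fits on single mice. Selected against control mice gave 308 genes in a fit on single mice, while the 2 genes came from line sums. These counts are not like measures. The tests between lines judged all line terms jointly against the spread of mice within lines. The fit that gave 308 judged a single difference against a spread that includes line differences. Of 16812 genes tested both between control lines and between selected lines, 440 differed in both, where independent lists would share 91. Leaving out 1 line gave 686 (L2) to 1294 genes between control lines and 660 (L8) to 868 between selected lines. Without L1 or L5 the control count was 826 or 827, and without L6 the selected count was 781.

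Between control lines the genes of lowest p often set a pair of lines apart from the other pair. Rps3a1 was at 69.4 CPM ± 1.92 in L1 (SD, n = 3) and 69.2 ± 4.01 in L2, but at 162 ± 9.23 in L4 and 215 ± 10.7 in L5 (SD, n = 4 each), while its pseudogene Rps3a3 was at 66.7 and 63.6 in L1 and L2 and at 0.572 and 1.07 in L4 and L5. Pop4, a subunit of RNase P, was at 7.07 and 8.03 CPM in L1 and L5 and at 23.2 and 23.8 in L2 and L4. Metap1d, a mitochondrial aminopeptidase, was at 28.9 and 27.7 in L1 and L4 and at 8.85 and 9.32 in L2 and L5, and the noncoding 1500004A13Rik was at 63.9 and 63.0 in L2 and L4 and at 0.364 and 0.874 in L1 and L5. Cox7b, a subunit of cytochrome oxidase, was at 108 ± 4.93 in L1 and at 236 to 258 in the other lines. The pseudogenes Gm8225 and Gm12245 were at 1.66 and 2.92 in L1 and at 0.0581 and 0.0213 in L5. Rps3a1, Rps3a3 and the 2 pseudogenes can share reads with their copies, and Metap1d and 1500004A13Rik overlap other genes, so these 6 are uncertain. All 8 genes had edgeR adjusted p of 7.66e-09 or less. Of the microglia markers 8 of 15 differed between control lines, and the list score ran from -0.167 in L4 to 0.144 in L5.

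Between selected lines the genes of lowest p often set 1 line apart. In L8, Serinc4 was at 9.94 CPM ± 1.41 against 0.383 to 0.432 in the other lines, Hmga1b at 5.24 ± 0.298 against 0.661 to 0.789, and the pseudogene Gm9816 at 18.2 ± 0.664 against 2.58 to 2.68 (SD, n = 4 mice). In L3 the noncoding AA465934 was at 15.6 ± 1.25 against 2.12 to 2.79, and in L6 the pseudogene Gm8399 was at 30.4 ± 3.89 against 1.08 to 1.19. AK157302 was at 19.2 and 14.4 CPM in L3 and L7 and at 0.0259 and 0.0178 in L6 and L8, and Rpl15-ps2 at 6.46 and 7.32 in L3 and L7 and at 0.0154 and 0.0388 in L6 and L8. Tmem181c-ps was at 43.2 ± 2.82 in L3 and at 4.29 to 9.59 in the others. The 4 pseudogenes, Hmga1b, a near copy of Hmga1, and Serinc4 and AA465934, which overlap other genes, are uncertain. All 8 had adjusted p of 3.89e-10 or less.

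The fourth question was whether genes follow the distance a mouse ran within its line. No gene of 17432 passed in edgeR, with 1391 at unadjusted p under 0.05 where 872 were expected. The lowest adjusted p was 0.0844, for Pilra, an inhibitory receptor of myeloid cells (log2 0.12 per km, SE 0.0218), and Inpp5j, an inositol phosphatase (0.02 per km, SE 0.00416). The other genes of lowest p with positive slopes were Lrrc32 (0.04), Scrt2 (0.03) and Pim3 (0.02). Those with negative slopes were Fdps, a synthase of the cholesterol pathway (-0.02), the immunoglobulin gene Ighg2c (-0.18), the linker histone H1f0 (-0.02), 2810459M11Rik (-0.03) and Slc37a1 (-0.05), all in log2 per km. No gene passed for a difference of slopes between selected and control mice (edgeR, 0 of 17432, with 1361 at unadjusted p under 0.05). Without the L5 mouse of highest ambiguous share Arhgap27os1 passed (adjusted p = 0.0125). Pilra, Inpp5j and Arhgap27os1 overlap other genes and are uncertain. Without the L7 mouse of lowest distance, whose 1584 m is also the label of an L1 mouse, 919 genes had an unadjusted p under 0.05 within lines. Scores of the 31 lists gave a lowest permutation p of 0.0143 for striatal projection neuron genes (0.353 after adjustment over 31 lists).

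The last question was whether selected lines use other exons of the same genes. Of 14855 gene models with 235792 bins, 60 passed, among them 12 merged models, and 25 of the 60 had a leading bin in which the 4 selected lines all lay outside the control range. On simulated counts 69 of the 215 calls of this test were false (32.1%). That is more than the 60 calls made here, so false calls alone could supply the count. Of the 60, 47 were also among the 118 models called by limma's diffSplice on the same bin counts. In the simulation 86 of the 243 calls of diffSplice were false (35.4%), so the overlap is not independent support. In Tmed5 bin 4 took 41.0% ± 2.19 of the gene's bin counts in control and 26.5% ± 0.209 in selected lines (SD, n = 4 lines, adjusted p = 3.86e-11). In Dnajb6, a co-chaperone, bin 27 took 6.58% ± 0.379 and 2.18% ± 1.69. Bins with a larger share in selected lines were bin 17 of 3110039I08Rik (0.851% and 3.49%), bin 4 of Rrbp1, a ribosome-binding protein of the endoplasmic reticulum (1.54% and 3.89%), bin 36 of Lig3, a DNA ligase (0.50% and 1.77%), and bin 22 of Cdk11b (0.0244% and 0.129%). The merged models Gm27348/Lrp1b (0.0972% and 0.662%) and Mettl17/Slc39a2 (0.57% and 0.13%) join overlapping genes and are uncertain. So are the bins of 3110039I08Rik, whose span holds Gm8707, and those of Tmed5 and Lig3, which overlap other genes. Bin 22 of Cdk11b is uncertain too, since a share of 0.0244% leaves few reads in control lines.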

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

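In this part the tests on exon bins and on microglia were chosen after the results were seen. Of 91 groups of 4 values searched for a sample far from the rest, 10 passed Dixon's 95% critical value, where chance gives about 4.6, or 1 in 20 groups. Most of the 10 were shares of read pairs at ambiguous positions, and the excess came from these. The passes among CPM values and list scores were no more than chance would give.

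Among the selected lines L3 stood apart for 5031434O11Rik, at 2.03 CPM with the other lines at 0.65 to 0.677 (gap divided by range 0.981), and for Rhbdl3, at 44.1 CPM with the others at 41.8 to 42.1 (0.846). Among the control lines L5 stood apart for Cdk11b, at 63.6 CPM with the others at 66.2 to 66.3 (0.933). L2 stood apart for the score of antigen presentation and interferon genes, at -0.101 with the other control lines at 0.205 to 0.26 (0.849). In 6 of the 7 lines with 4 mice, 1 mouse had a higher share of read pairs at ambiguous positions in the exon-bin counts than the rest of its line. These were 0.438% in L2 (gap divided by range 0.953), 0.266% in L3 (0.927), 0.534% in L4 (0.911), 1.804% in L5 (0.874), 0.362% in L7 (0.841) and 0.696% in L8 (0.958), with the other mice of these lines at 0.13 to 0.405%. The L5 mouse also had the highest share of gene-level ambiguous pairs, 3.33%.

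The list of antigen presentation and interferon genes stood lower in selected lines, with a score difference of -0.295 (SE 0.115), and 3 of the 35 divisions of the lines into 4 and 4 gave one as large (highest other 0.347), so chance cannot be excluded. A smaller number of microglia is argued against, since the microglia score differed by 0.016 (SE 0.095). Haplotypes of the major histocompatibility region that differ by line may be the source: the 10 members on chromosome 17 differed by -0.447 (SE 0.171) and the 14 elsewhere by -0.186 (SE 0.129). That last value lies between the bounds set in advance, so a difference of that region alone and one of the whole list cannot be told apart. A response to selection for running also stays open and was not tested.

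Genes of low p lay near each other, with 22 pairs within 1 Mb among the 100 genes of lowest p. As many pairs or more were found in 22 of the 35 divisions of the lines (highest other 223), so chance cannot be excluded for their number in this division. Gene density is argued against as the whole source, since 2 of 10000 random sets of 100 tested genes held as many (highest 24). Loss of reads at variants in single exons was examined in the 21 of 26 paired genes with at least 3 bins. There the median bin carried 0.92 of the gene's log2 fold change (quartiles 0.51 and 0.99, 5 genes under 0.5). This argues against such loss as the source in most of these 21 genes, though the median weighs bins of few reads like those of many. In Tmed5, where the median bin carried 0.79, bin 4 took 41.0% of the bin counts in control and 26.5% in selected lines. Such loss therefore stays open for Tmed5, for those 5 and for genes with fewer bins, such as Mfsd7a. Chromosome segments shared by the mice of a line, through drift or selection, may be the source, and they were not tested because genotypes were not analysed here.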

How the results depend on the processing

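All 20 genes named for selection kept their sign in all of 355 alternative values, of which 313 stayed on their side of the threshold, 11 lost the call and 31 gained it. The sign had little room to change. These genes were picked from the same counts, and in each the selected lines stood apart from the control lines. Adjusted p of Gm8707 ran from 8.81e-21 to 0.122 and of Mfsd7a from 1.17e-14 to 0.122, above 0.05 for both without L1, L3, L6, L7 or L8 and for Mfsd7a also without L5 (0.0554). Over the same alternatives the log2 fold change ran from -1.237 to -1.051 for Gm8707 and from -1.444 to -1.293 for Mfsd7a. The count over lines was 2 with other size factors, with none, without a filter, on autosomes, without the L7 mouse and without the L5 mouse. It was 3, all lower, with limma on line means, 50 with DESeq2, 45 with limma-voom and line as a random block, 1 at a mean log2 CPM of at least 1, which leaves out Mfsd7a, and 0 to 7 with 1 line left out (0 without L1, L6, L7 or L8, 1 without L3, 6 without L2, 7 without L4). Over mice it was 546 with DESeq2 (284 higher, 262 lower) and 82 to 727 with 1 line left out. Between control lines it was 686 to 1294 and between selected lines 660 to 868 with 1 line left out, where fewer samples and fewer lines enter. No gene passed for running distance in edgeR under any of its 8 alternatives, with 919 to 1977 at unadjusted p under 0.05. For the difference of slopes 1 gene passed without the L5 mouse, Arhgap27os1 (adjusted p = 0.0125, and 0.398 with that mouse), named after its value was seen. Exon usage gave 93 gene models by F test and 118 by limma, and 50 to 85 with 1 line left out. Of the 31 lists, 0 passed with an estimated correlation, 0 with fry and 4 (L2 or L6) to 12 (L1) with 1 line left out. The running ratio ran from 3.57 to 4.53, with an exact p of 0.0286 throughout. That is the lowest value these numbers of lines allow, so it shows only that the groups stayed apart. Except where stated, the cause was not tested. The alternatives without the L5 mouse, without the L7 mouse over mice and without a filter for running distance were chosen after the data were seen. Depth limits genes of low count, such as Mgst2 at 0.0662 CPM.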

Other observations

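Of the tests in this part, those on the choice of lists, on clock genes, on single lists without a line, on list scores against running distance, on running distance without the L7 mouse and on counts of genes at unadjusted p under 0.05 or without overlap between selected and control lines were chosen after the results were seen.

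Cortical excitatory neuron markers passed camera at the preset correlation, but not with an estimated one (adjusted p = 0.906) or with line as a random block (0.669). No other list of cell type markers passed between selected and control lines. Camera adjusted p was 0.943 for direct-pathway and 0.983 for indirect-pathway projection neuron markers, 0.626 for genes of all striatal projection neurons and 0.943 for interneuron markers. It was 0.626 for astrocytes, 0.943 for oligodendrocytes, 0.626 for microglia, 0.285 for endothelial and mural cells, 0.943 for blood, 0.579 for choroid plexus and ependyma, and 0.983 for thalamic, septal and hypothalamic markers. With 1 line left out, some of these lists passed with higher values in selected lines: genes of all striatal projection neurons without L8 (adjusted p = 0.000535) or L1 (0.0249), endothelial and mural markers without L1 (0.0387), and choroid plexus and ependymal markers without L4 (0.0268). Choroid plexus and ependymal markers had the widest spread between lines, with scores from -0.723 in L1 to 0.869 in L3. Among indirect-pathway markers Upb1, an enzyme of pyrimidine breakdown, was at 0.642 CPM ± 0.118 in control and 1.15 ± 0.334 in selected lines. It rose over lines when adjusted over the list alone (0.0392) and over mice among all genes (0.00785), but not over lines among all genes (0.738), and it overlaps Gucd1 and is uncertain.

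Genes of neuronal signalling gave camera adjusted p of 0.983 for glutamate receptors, 0.579 for GABA receptors, 0.943 for opioid and cannabinoid genes, 0.943 for neuropeptides and their receptors, 0.943 for voltage-gated potassium channels and 0.167 for neurotrophins and growth factors, which passed with higher values without L3 (0.0475). Oxidative phosphorylation genes gave 0.943, although Ndufc1 rose over mice (log2 fold change 0.16, adjusted p = 0.0341). That list passed in opposite directions with 1 line left out, lower in selected lines without L1 (0.00611) and higher without L5 (0.0188). The sign of the median, the mean or the test differed in 7 lists that did not pass, namely serotonin receptors, direct- and indirect-pathway markers, oxidative phosphorylation, oligodendrocytes, blood and thalamic markers.

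Heat shock, immediate early and clock genes stood higher together in the selected lines, and a hypothesis is that these mice were more aroused or at another hour of their day when sampled. Arousal was not tested. The mean score of the 3 lists differed by 0.121 (SE 0.051), and 1 of 35 divisions of the lines gave as much (highest other 0.112), but the lists were picked because they stood higher in that same division, so this says little. Choosing among 31 lists could account for it, since 20 of the 35 divisions had a list of their own with a camera p as small (lowest 6.78e-30). Whether a single line carries it cannot be told apart, since without L5 the difference was 0.076 (SE 0.026), 0.63 of its value, and 0.5 of the value lies within that spread. The rule set in advance did not count the spread. Under it, the 0.63 would have counted against a single line. At least 0.71 of the difference of heat shock genes and 0.64 of that of immediate early genes was left without 1 line, likewise within their spread of 0.5. For clock genes 0.46 was left without L5, so that line may carry most of it. An earlier or later hour cannot be told apart, since Per1, Per2, Per3, Dbp, Tef, Nr1d1 and Nr1d2 differed by 0.103 (SE 0.092) and Arntl, Npas2 and Clock by 0.073 (SE 0.061), both within 2 SE of 0, a bound tightened from 1 SE after these values were seen. Both exceeded 1 SE with the same sign, so at the earlier bound they would have counted against another hour.

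Counts were compared with those of other divisions of the same samples. Of the 35 divisions of the lines, 8 called at least the 2 genes of selection over lines (highest other 12), 6 called at least 308 over mice (545), 14 called at least 60 gene models in exon usage (104) and 20 called at least 8 lists (16), so chance cannot be excluded for any of these 4 counts. Nor can it for the 1173 genes at unadjusted p under 0.05 over lines (10 of 35, highest other 1995) or the 738 without overlap of the groups (6 of 35, highest other 1123). With single mice moved between groups, 2 of 100 divisions, the real one among them, called at least 308 (highest other 879, above the real count, which may come from a structure of the samples that was not tested). A chance assignment of single mice thus seldom gave as many but is not excluded, and neither is one of whole lines. For differences between control lines and between selected lines chance is excluded, as 1 of 100 assignments gave as many in each case, the real one (1360 and 1181 genes, highest other 123 and 39). For running distance within lines, 2 of 60 assignments, the real one among them, gave at least 1391 genes at unadjusted p under 0.05 (highest other 1803). Chance thus seldom gave that count but is not excluded for it, and no single gene passed. The count rests on the L7 mouse of lowest distance: without it 11 of 60 gave at least the 919 left (highest other 1749), so chance cannot be excluded there. That mouse, L7.1, carries the same labelled distance as L1.3, 1584 m, so 1 of the labels may be wrong, which was not tested. For the difference of slopes 6 of 60 gave at least 1361 (highest other 2185), so chance cannot be excluded.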
